A study of Mus musculus with 12 samples.

How the data were processed

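The deposited files were 12 MACS2 broad peak lists, 1 per library; no reads, read counts or coverage tracks were analysed here, so sequencing depth could not be used. Per the submitters' processing notes, reads were aligned to mm10 with BWA 0.7.17 and handled with SAMtools 1.9, bedtools 2.30 and deepTools 3.5, and the authors called peaks in each library with MACS2 2.2.7.1. Coordinates in the deposited lists were taken as zero-based starts on mm10, as the authors' build states. The deposited score was 10 times the −log10 q, shortened to a whole number, in 99.96 to 99.99% of the peaks of a list. The score was not used. The deposited fold column, a ratio of pileup over background, was not compared between libraries. The deposited −log10 p and −log10 q were used only to rank or filter peaks within a list, because they depend on depth. Group, guide, vector and time after estrogen removal were taken per the labels. Analyses used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

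Genes were the 21887 protein-coding genes of the GRCm38.p6 table, which has the coordinates of mm10. That table has no strand, so the planned windows around transcription starts were replaced by the gene span ± 50 kb, and promoters by regions within 1 kb of either gene end. No genome sequence came with the series, so the planned motif content was not run.

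Library measures and chromosome shares were compared by exact permutation tests. The 3 against 3 comparisons have 10 distinct splits and a smallest p of 0.1, and the 6 against 6 comparisons permuted labels within the other factor, with 400 arrangements and a smallest two-sided p of 0.005. Benjamini-Hochberg adjustment was made over 32 library tests and over 40 chromosome tests. Similarity was the Jaccard index of covered bases, tested over 100000 random arrangements for the 4 groups and over 400 exact arrangements for each factor. Peaks overlapping by at least 1 bp were merged to 56682 regions, of which 37113 were found in at least 2 libraries and 13356 in all 12. A region counted as gained when it had a peak in all 3 libraries of the tested group and none of the other 3, and as lost in the opposite case. A region counted for a factor when this held in both backgrounds. Each region was also tested by an exact stratified test for each factor, with Benjamini-Hochberg adjustment over 37113 regions.

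For each gene the peak-covered length in its window was scaled to equal total covered length, 500 bp were added, and log2 values were fitted with limma (trend) to the 4 groups with all 12 libraries and 8 residual degrees of freedom. The 15286 genes with a mean of at least 500 bp were tested, and genes with an adjusted p below 0.05 (Benjamini-Hochberg per comparison) are said to have risen or fallen. T618I and sgB2 effects are means over the other factor, and the interaction is the difference between the T618I changes in sgB2 and sgNT cells. Group values of genes are scaled kb. Genes in overlapping windows share peaks and were also counted as loci. The 15 gene lists, with 281 genes of which 279 were in the reference, were written from general knowledge before the data were examined and tested with limma's camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the 15 lists. The adjustment over the list alone used the limma p-values of its members. Named genes were the 5 largest changes per direction among those that passed, at most 4 members per list by p-value, and the engineered genes; regions were up to 8 per direction with the highest mean within-library rank, 1 per gene. Other splits of the libraries were all 10 for a comparison of 3 against 3 and 100, the real one included, for a factor. One item withheld for evaluation, and the results that need it, are not reported here. The 10-Mb bins were those with at least 120 peaks over all libraries.

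The contrasts, tests, lists and most alternatives were fixed before the data were examined. The alternatives without chromosomes 1 and X, the alternatives of the chromosome shares and 1 list member per locus were added afterwards. The procedures were tested on simulated data for T618I in sgNT cells. The region rule found 200 of 200 planted regions and 144 others. The gene fit found 82 of 100 genes planted at a log2 change of 1 and 13 of 100 at 0.5. Changes under about 1 were therefore often missed in 3 against 3 comparisons. It called 6 other genes, and 0 genes in an unchanged comparison. Genes were simulated independently, without shared windows or shifts of whole libraries or chromosomes, so these counts of false calls may be too low for the real data.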

Results

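Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse HoxB8 cells. These are bone marrow progenitors immortalised by the transcription factor Hoxb8 and kept in estrogen and stem cell factor. All 12 libraries were made 48 h after estrogen had been removed, which lets such progenitors mature. The cells carried either a non-targeting guide (sgNT) or a guide against Asxl1 (sgB2), made to truncate the Polycomb-associated protein Asxl1. Each also carried a vector that was empty or expressed CSF3R T618I, a mutant form of the receptor for granulocyte colony-stimulating factor. The 4 groups, sgNT/Empty, sgB2/Empty, sgNT/T618I and sgB2/T618I, had 3 libraries each, so that each mutation could be compared with the control alone and on top of the other. The labels do not say whether the 3 libraries of a group came from separate cultures. The limma and permutation p-values therefore measure only the spread between these libraries, whatever its source. Camera compares the genes of a list with all other genes. Its p-values therefore depend on the number of genes and the variation between them, and very small ones do not show agreement between libraries.

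The data were 1 list of peaks per library on build mm10. The lists held 18484, 26579 and 29699 peaks in sgNT/Empty, 20293, 25252 and 25891 in sgB2/Empty, 28584, 26112 and 29642 in sgNT/T618I, and 24995, 32975 and 23695 in sgB2/T618I, and they covered between 9.23 and 17.9 Mb. They carried no read counts, so the sequencing depth was unknown and no counting interval could be given. T618I libraries had 27667 ± 3413 peaks (SD, n = 6) and Empty libraries 24366 ± 4187, which did not differ by an exact permutation test (two-sided p = 0.245). The median peak was 430 ± 25 bp wide with sgB2 and 473 ± 32 bp with sgNT (SD, n = 6; exact p = 0.005, adjusted p = 0.16 over 32 comparisons). With T618I it was 38.2 bp wider than with Empty (exact p = 0.025, adjusted p = 0.4). No library measure differed after adjustment, which the 20 of 32 tests of 3 against 3 libraries could not have done. Libraries of the same group shared more covered bases than libraries of different groups, with a mean Jaccard index of 0.592 within and 0.542 between groups (permutation p = 0.00072, one-sided). In the deposited lists this did not hold for each group: sgNT/Empty libraries shared 0.553 with each other and 0.555 with sgNT/T618I, and sgB2/T618I libraries 0.577 with each other and 0.581 with sgNT/T618I. In equal-length lists it did hold for these groups (0.634 against 0.616 for sgNT/Empty, and 0.672 against 0.656 for sgB2/T618I). T618I and Empty libraries of the same guide were further apart than libraries of one group by 0.0516 (exact one-sided p = 0.01), whereas the corresponding difference for the guide, 0.0257, did not pass (exact one-sided p = 0.06). The guide difference did pass in equal-length lists (0.0351, exact one-sided p = 0.02) and in 5 of 12 fits with 1 library left out.

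The engineered genes were examined first. At Asxl1 (chromosome 2, 153345830 to 153404007), the peak at the gene end (153345409 to 153346618) and a second inside the gene (153350593 to 153351189) were found in all 12 libraries. Peak coverage around the gene did not differ with sgB2 (log2 change -0.00 ± 0.16, SE; adjusted p = 0.998). A peak list cannot show a small insertion or deletion, so the edit itself was not checked. At Csf3r (chromosome 4, 126023441 to 126044975), the peak at 126024127 to 126025120 was present in all 12 libraries. Coverage rose with T618I from 3.10 ± 0.27 and 2.93 ± 0.44 kb in the Empty groups to 4.53 ± 0.20 and 4.33 ± 0.09 kb (SD, n = 3; log2 change 0.49 ± 0.08, limma adjusted p = 0.00206). That rise was not called with a 10 kb window, with stricter peaks or with equal-length lists. Reads from a vector insert cannot be told apart from reads of the endogenous gene in these lists. Hoxb8 (chromosome 11, 96279401 to 96285325) had a peak inside the gene in 2 of 12 libraries. Its coverage did not differ with T618I (-0.06 ± 0.16, adjusted p = 0.857) or sgB2 (-0.22 ± 0.16, adjusted p = 0.589).

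The first comparison asked what CSF3R T618I does to open chromatin, averaged over both guides (6 T618I against 6 Empty libraries). Peak coverage within 50 kb rose around 621 genes in 337 separate loci and fell around 371 genes in 211 loci, of 15286 genes tested. The largest gain was at F2rl2, a protease-activated receptor (chromosome 13, 95696920 to 95702768). Coverage there was 0.28 ± 0.32 and 0.32 ± 0.17 kb in sgNT/Empty and sgB2/Empty and 2.37 ± 0.34 and 3.56 ± 0.73 kb in the T618I groups (SD, n = 3; log2 change 2.13 ± 0.17, SE; limma adjusted p = 2.5e-06). Adam19, a membrane metalloprotease (1.84 ± 0.29), the microtubule gene Map10 (1.67 ± 0.23) and the stefin genes Cstdc4 and Stfa2l1 (both 1.62 ± 0.13) followed. The stefins are cysteine protease inhibitors, and the pair on chromosome 16 share a window. Coverage fell most around Maf, a transcription factor of macrophages and lymphocytes (-1.21 ± 0.19, limma adjusted p = 0.00135). The proteoglycan genes Prelp (-1.20 ± 0.13) and Optc (-1.13 ± 0.13) on chromosome 1 followed, which are neighbours with overlapping windows. The monocarboxylate transporter gene Slc16a7 (-1.17 ± 0.18) and Ankrd24 (-1.12 ± 0.17) fell too. The balance of gains and losses followed the scaling. Without scaling to equal total coverage, 837 genes rose and 16 fell, with the median of all genes shifted to 0.20 from -0.05. All changes here are therefore relative to the total coverage of a library. Counts fell to 372 genes with a 10 kb window, to 642 with the number of peaks as a covariate and to 587 without sgNT/T618I replicate 1.

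Genes of mature neutrophils gained coverage as a group with T618I. Of 20 measured members, 10 rose, none fell and 10 did not pass, and 15 rose adjusted over the list alone. Their mean coverage was 3.09 ± 0.23 kb in sgNT/Empty and 2.97 ± 0.17 kb in sgB2/Empty, against 4.05 ± 0.05 kb in sgNT/T618I and 3.84 ± 0.11 kb in sgB2/T618I (SD, n = 3). Retnlg, a resistin-like secreted protein of granulocytes, rose by 1.0 ± 0.16 (SE, log2), the decoy interleukin receptor Il1r2 by 0.90 ± 0.14, the chemokine Ccl6 by 0.68 ± 0.11 and Csf3r itself by 0.49 ± 0.08. The list's median log2 change was 0.42 (camera adjusted p = 1.4e-12; adjusted p = 0.0103 with an estimated correlation). Genes listed for secondary and tertiary granules, which neutrophils fill late in maturation, also rose as a group. Of 20 members 5 rose, none fell and 15 did not pass, with 7 rising adjusted over the list alone. Cd177, a neutrophil surface glycoprotein, rose by 1.16 ± 0.16 and the collagenase gene Mmp8 by 0.84 ± 0.14. On this list too were S100a9 and S100a8, the subunits of calprotectin, which rose by 1.04 ± 0.08 and 1.0 ± 0.09. Their windows overlap (chromosome 3, 90692630 to 90695721 and 90669071 to 90670034), so these risen members share peaks. The list's median was only 0.11, and camera gave an adjusted p = 1.4e-05, or adjusted p = 0.0352 with an estimated correlation. With stricter peaks the list did not pass (adjusted p = 0.138).

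Primary granule genes, which are active in promyelocytes, moved the other way in part. Of 12 members 3 fell, 1 rose and 8 did not pass (2 up and 3 down adjusted over the list alone). Coverage fell around Mpo, the myeloperoxidase gene, from 8.74 ± 1.81 and 7.90 ± 0.60 kb to 6.26 ± 0.60 and 5.27 ± 0.27 kb (SD, n = 3; log2 change -0.49 ± 0.09, limma adjusted p = 0.00415). It also fell around the neighbouring protease genes Prtn3 (-0.37 ± 0.08) and Elane (-0.34 ± 0.09). It rose around Ctsc, whose product activates those proteases (0.63 ± 0.17, adjusted p = 0.0325). As a list they did not pass camera (median -0.14, adjusted p = 0.241), but did, downward, in 3 of 21 alternatives (adjusted p = 0.0103 in equal-length lists; adjusted p = 0.0882 with an estimated correlation). None of these 3 calls was kept with an estimated correlation. The losses at Mpo, Prtn3 and Elane were not called without scaling, and that at Elane was lost in 7 further alternatives.

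**Figure D1:**
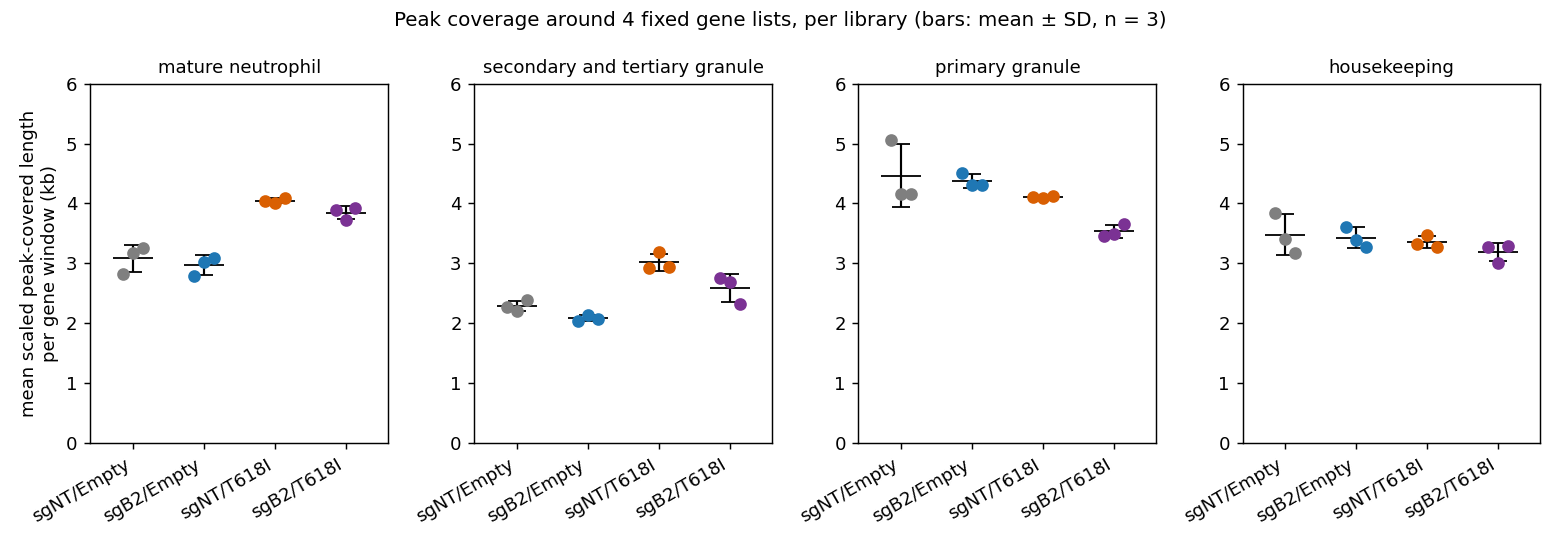
Mean scaled peak-covered length per gene window (kb) over the members of 4 fixed gene lists, for each of the 12 libraries by group. Points are libraries and bars the mean ± SD (n = 3); the mature neutrophil means were 3.09 and 2.97 kb in the Empty groups and 4.05 and 3.84 kb in the T618I groups, and primary granule genes were lowest in sgB2/T618I at 3.54 kb.

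Inflammatory genes of the NF-kB and AP-1 list rose with T618I. Of 20 members 3 rose, none fell and 17 did not pass, and 4 rose adjusted over the list alone (median 0.16, camera adjusted p = 0.000595, or adjusted p = 0.0225 with an estimated correlation). Coverage around the cytokine gene Il6 rose from 0.14 ± 0.13 and 0.24 ± 0.02 kb to 0.81 ± 0.27 and 1.37 ± 0.14 kb (log2 change 1.18 ± 0.14, limma adjusted p = 0.000148). The chemokine genes Ccl4 (0.69 ± 0.12) and Ccl3 (0.55 ± 0.13), which are neighbours, rose too. Their windows overlap that of Ccl6 on the mature neutrophil list, so in every comparison some peaks can count in both lists. JAK-STAT targets had 1 of 20 members that rose, the interleukin receptor gene Il4ra (1.11 ± 0.17), none that fell, and the same count adjusted over the list alone. Their camera adjusted p was 0.0391, with adjusted p = 0.29 with an estimated correlation. The interferon response list had no member of 16 past the test, nor any adjusted over the list alone, and also lost its camera call (adjusted p = 0.0391; adjusted p = 0.104 with an estimated correlation).

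Markers of other lineages were followed in the same way. Lymphoid genes fell in 2 of 14 members (5 adjusted over the list alone), namely Ebf1, a B cell transcription factor (-0.64 ± 0.13), and Vpreb1, a part of the pre-B cell receptor (-0.51 ± 0.11). For this list camera gave adjusted p = 0.0431, and adjusted p = 0.106 with an estimated correlation. In the stem and progenitor list, Kit, the stem cell factor receptor, fell (-0.59 ± 0.12, limma adjusted p = 0.00853). The other 14 of 15 members did not pass (1 up and 2 down adjusted over the list alone; camera adjusted p = 0.575). One of 18 monocyte, macrophage and dendritic genes rose, Ccr2 (0.47 ± 0.12; 1 adjusted over the list alone; median 0.01, camera adjusted p = 0.575). Of 14 erythroid and megakaryocyte genes the platelet gene Gp9 fell (-0.38 ± 0.09; 1 adjusted over the list alone; camera adjusted p = 0.919), with the opposite sign in a 10 kb window. Of 13 mast cell, basophil and eosinophil genes Hdc, the histidine decarboxylase gene, rose (0.59 ± 0.16; 2 adjusted over the list alone), the median was -0.13 and the camera direction was up (adjusted p = 0.974). Of 20 myeloid transcription factor genes Spi1 rose (0.28 ± 0.08; 3 up and 2 down adjusted over the list alone; camera adjusted p = 0.251). Of 19 Polycomb and ASXL-BAP1 subunit genes Asxl1 (0.57 ± 0.16, adjusted p = 0.0393) and Eed (0.41 ± 0.10) rose, both also adjusted over the list alone (camera adjusted p = 0.974). Eed had the opposite sign in a 10 kb window. Only 4 of 20 developmental Polycomb targets were measured and 1 fell, the paired box gene Pax2 (-1.07 ± 0.23; 1 adjusted over the list alone; camera adjusted p = 0.129). Housekeeping genes had 2 members that rose, Pgk1 (0.67 ± 0.11) and Snrpd3 (0.36 ± 0.10, with the opposite sign in a 10 kb window), and 1 that fell, Polr2a (-0.38 ± 0.08), of 20 (3 up and 3 down adjusted over the list alone; camera adjusted p = 0.589).

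In cells with the non-targeting guide alone (3 T618I against 3 Empty libraries), T618I raised coverage around 178 genes (100 loci) and lowered it around 50 (39 loci). Nrp2, a semaphorin coreceptor, rose from 0.46 ± 0.45 to 3.06 ± 0.20 kb (SD, n = 3; log2 change 2.02 ± 0.30, limma adjusted p = 0.00231). It was followed by the carcinoembryonic family gene Ceacam10 (1.97 ± 0.29), F2rl2 (1.95 ± 0.24), Cd177 (1.76 ± 0.22) and Gm15448 (1.72 ± 0.29). Ceacam10 and Cd177 are close together, with overlapping windows. Slc16a7 fell from 1.22 ± 0.35 kb to no coverage in the 3 T618I libraries. Losses followed at Npas3 (-1.64 ± 0.25), Maf (-1.46 ± 0.27), Nme9 (-1.46 ± 0.21) and Prelp (-1.43 ± 0.18). Of the mature neutrophil list, 2 members rose (Retnlg, 1.55 ± 0.23, and Csf3r, 0.49 ± 0.12, just under the threshold of 0.05). In this list 11 rose adjusted over the list alone (median 0.51, camera adjusted p = 5.4e-12; adjusted p = 0.0121 with an estimated correlation). Of the secondary and tertiary granule genes 4 rose, with 6 adjusted over the list alone (camera adjusted p = 4.3e-06; adjusted p = 0.0407 with an estimated correlation). The inflammatory list had 1, Il6 (1.03 ± 0.20; 1 adjusted over the list alone; camera adjusted p = 0.0104; adjusted p = 0.0497 with an estimated correlation). That list's call was lost with a 10 kb window (adjusted p = 0.254) and with 1 member per locus (adjusted p = 0.0747). Leaving out sgNT/T618I replicate 2 lowered the number of genes from 228 to 63, and leaving out scaling gave 59 that rose and 0 that fell.

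On top of the Asxl1 guide (3 sgB2/T618I against 3 sgB2/Empty libraries), T618I raised coverage around 185 genes (113 loci) and lowered it around 60 (40 loci). F2rl2 (2.31 ± 0.24, adjusted p = 0.000137) and Adam19 (2.28 ± 0.41) led again, before Gm5150 (1.94 ± 0.28) and the stefin pair Cstdc4 and Stfa2l1 (1.72 ± 0.18). Amot, a cell junction gene on the X chromosome, went from 1.31 ± 0.16 kb to no coverage (SD, n = 3; log2 change -1.85 ± 0.17, limma adjusted p = 7.0e-05). Losses followed at Xaf1 (-1.80 ± 0.27), Pax2 (-1.58 ± 0.33) and the neighbours Ankrd24 (-1.44 ± 0.24) and Sirt6 (-1.42 ± 0.23), whose windows overlap. Of the mature neutrophil list 3 members rose, Il1r2 (1.07 ± 0.20), Ccl6 (0.78 ± 0.15) and Csf3r (0.50 ± 0.12), the last with the opposite sign in a 10 kb window (-0.13) and in equal-length lists. Adjusted over the list alone 7 rose (median 0.31, camera adjusted p = 1.4e-08; adjusted p = 0.025 with an estimated correlation). In the secondary and tertiary granule list 2 members rose, the calprotectin genes S100a9 and S100a8, whose windows overlap. In this list 5 rose adjusted over the list alone (camera adjusted p = 0.000787, or adjusted p = 0.0983 with an estimated correlation). That call was lost with stricter peaks (adjusted p = 0.932) and equal-length lists (adjusted p = 0.386). In the inflammatory list 2 rose, Il6 (1.33 ± 0.20) and Ccl4 (0.83 ± 0.17; 3 adjusted over the list alone; camera adjusted p = 0.000787; adjusted p = 0.025 with an estimated correlation). Among primary granule genes Prtn3 (-0.58 ± 0.12) and Mpo (-0.54 ± 0.13) fell, with 3 adjusted over the list alone (camera adjusted p = 0.0674). This list passed, downward, in 6 of 21 alternatives, but with an estimated correlation only for a 10 kb window (adjusted p = 0.000494; adjusted p = 0.0285 with an estimated correlation). Without scaling 35 genes rose and 1 fell, and leaving out sgB2/Empty replicate 1 lowered the number of genes from 245 to 92. Across the 15286 genes, the T618I changes in sgNT and in sgB2 cells, which share no library, had a Pearson correlation of 0.535 and a Spearman correlation of 0.460. Of the genes 69.4% had the same sign in both; genes are not independent replicates.

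**Figure D2:**
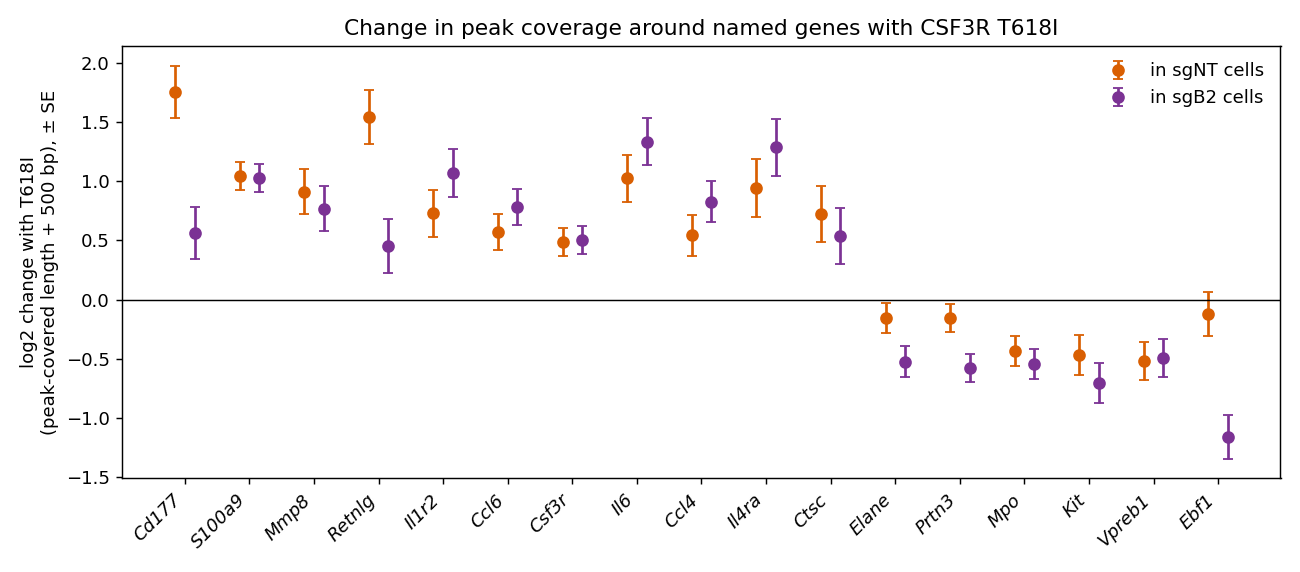
Log2 change in scaled peak-covered length (+ 500 bp) with T618I around 17 named genes, in sgNT cells and in sgB2 cells (3 against 3 libraries each). Points are limma estimates and bars ± SE; S100a9 rose by 1.05 and 1.03 in the 2 backgrounds, and Mpo had -0.44 and -0.54.

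Single regions showed the same comparison at finer scale. T618I gained 1204 regions in sgNT cells, meaning a peak in all 3 T618I libraries and none of the 3 Empty ones, and lost 204; in sgB2 cells it gained 1202 and lost 338. The 2 backgrounds shared 254 gained regions, where 39.0 would be shared if the lists were independent, and 32 lost regions, where 1.86 would be. These expectations count all 37113 regions, among them the 13356 found in all 12 libraries, which could not be gained or lost. They are therefore too low, and the size of the excess cannot be read from them. In equal-length lists the backgrounds shared 191 gains and 118 losses. Among the shared gains, the strongest lay within 1 kb of an end of the stefin gene Stfa2 (chromosome 16, 36408021 to 36408647, mm10). Others lay inside Ostf1 (chromosome 19, 18602981 to 18603430), inside Hcfc2 (chromosome 10, 82780403 to 82780641), and inside Dock2, a leukocyte migration gene (chromosome 11, 34525516 to 34525864). Among the shared losses were regions inside the adenylate cyclase gene Adcy2 (chromosome 13, 68928447 to 68928820), inside Inpp5d, which encodes the phosphatase SHIP (chromosome 1, 87640356 to 87640759), and 29545 bp from Cd9 (chromosome 6, 125430373 to 125430721). In the sgB2 background, a gain lay within 1 kb of an end of the interferon-induced gene Ifitm1 (chromosome 7, 140967779 to 140968504). Another lay inside the immune receptor gene Havcr2 (chromosome 11, 46466721 to 46467407). Each of these regions had a peak in 8 of 12 libraries, so sgNT libraries had it too, sgNT/Empty ones among them. The regions were thus missing in sgB2/Empty rather than open only with T618I. That they were gained in one background was not tested as a difference. An exact stratified test per region could not decide: its smallest p is 0.005, so at least 3712 regions would have to reach it before any passed the adjustment, and none did (0 of 37113, smallest adjusted p = 0.649). At an unadjusted p under 0.05, 845 regions were found more often and 126 less often with T618I. Among all testable regions 5% is 1183, but among those found in at least 3 libraries it is 909, with the same 845 and 126. The 5% figure therefore includes regions that could not reach this p, and it gives no chance level for these counts. The surplus of gains depended on the lists. In equal-length lists T618I gained 755 and lost 469 regions in sgNT cells and gained 722 and lost 630 in sgB2 cells. Without sgNT/Empty replicate 1, the shortest list, 1255 were gained and 1253 lost in sgNT cells.

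**Figure D3:**
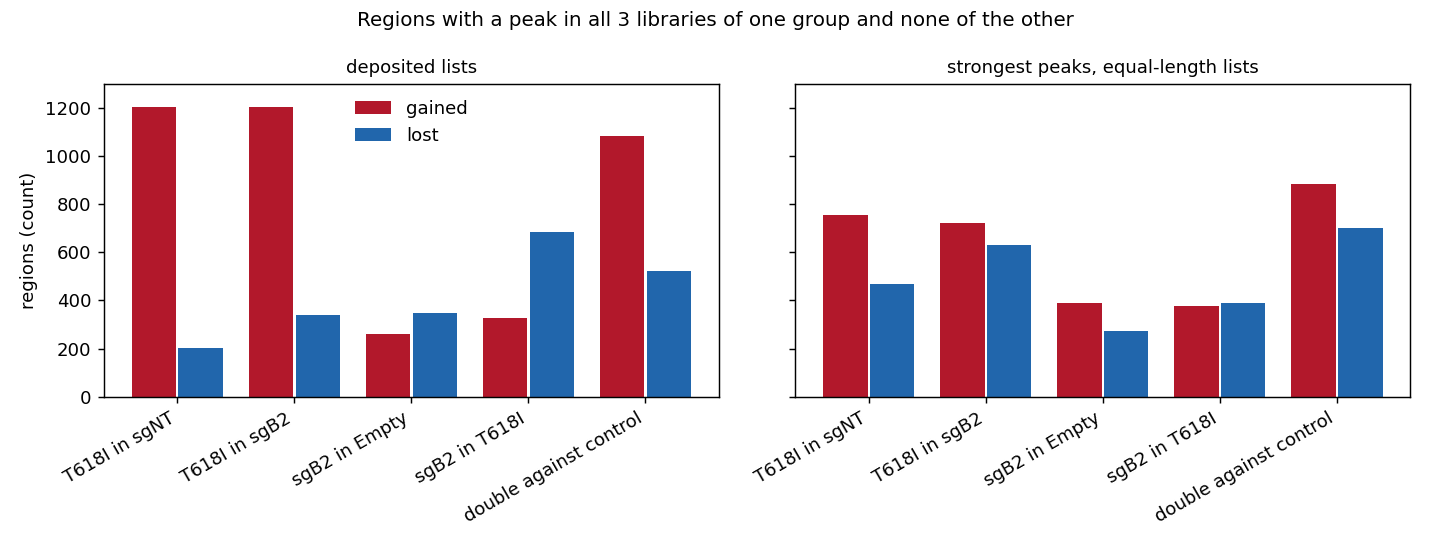
Number of regions with a peak in all 3 libraries of one group and none of the other, for 5 comparisons, in the deposited lists (left) and in lists shortened to the 18484 strongest peaks of each library (right). With T618I in sgNT cells gains outnumbered losses by 1204 to 204 in the deposited lists and by 755 to 469 in the equal-length lists.

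The next comparison asked what the Asxl1 guide does, averaged over both vectors (6 sgB2 against 6 sgNT libraries). Coverage rose around 233 genes (149 loci) and fell around 199 (141 loci). Bcl11a, a transcription factor of progenitors and B cells (chromosome 11, 24076564 to 24173558), went from 1.30 ± 0.25 and 0.90 ± 0.07 kb in the sgNT groups to 0.09 ± 0.16 and 0.05 ± 0.08 kb in the sgB2 groups (SD, n = 3; log2 change -1.49 ± 0.15, SE; limma adjusted p = 0.0003). The actin-bundling gene Pls3 on the X chromosome (-1.95 ± 0.28), Amotl2 (-1.50 ± 0.21), Calml3 (-1.44 ± 0.18) and Spp1, which encodes osteopontin (-1.35 ± 0.15), also fell. Gains were led by Akap6, a kinase anchoring gene (1.66 ± 0.21), Fmn2 (1.65 ± 0.21) and Rgs13 (1.40 ± 0.18) on chromosome 1. The neighbours Zfp467 (1.43 ± 0.26) and Krba1 (1.33 ± 0.24) on chromosome 6 rose too. Chromosome 1 held 154 of the 233 gains and none of the losses, of 945 genes tested there. Without chromosomes 1 and X, an alternative chosen after seeing the data, 52 genes rose and 139 fell, and without scaling 7 rose and 15 fell. In all gene counts without chromosomes 1 and X, scaling still used the total coverage with them. Their part in the scale was therefore not removed. The count of 432 genes became 122 with a 10 kb window, 122 with stricter peaks and 221 without sgNT/T618I replicate 1.

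Chromosome 1 stood apart over its whole length in the sgB2 libraries. It held 10.1% of the peaks in sgB2 libraries (range 9.48 to 11.2%) and 6.90% in sgNT libraries (6.67 to 7.05%), a ratio of 1.46. All 6 sgB2 libraries lay above all 6 sgNT libraries (exact two-sided p = 0.005, the smallest the design allows; adjusted p = 0.02 over 40 tests). Every one of its 20 bins of 10 Mb held a larger share in each sgB2 library than in any sgNT library, with a median ratio of 1.48, whereas 0 of 232 bins on chromosomes other than 1 and X did. The X chromosome held 1.85% of the peaks with sgB2 and 2.27% with sgNT (ratio 0.815, exact p = 0.005, adjusted p = 0.02). A larger share on chromosome 1 lowers the shares of the others, because they add up to the whole list. Chromosomes 5, 6, 9, 12, 15, 16 and 19 also fell with the same exact and adjusted p, at ratios of 0.949 to 0.969. The p-value is thus not particular to X, although its ratio was the lowest. In equal-length lists the ratios of chromosomes 1 and X were 1.24 and 0.923. With stricter peaks they were 1.22 and 0.907, and neither passed over 40 tests (exact p = 0.005 and 0.01, adjusted p = 0.0667 and 0.075). On chromosome 1 all sgB2 libraries still lay above all sgNT libraries in both alternatives. On X the ranges overlapped in both, with up to 2.18% with sgB2 and down to 2.11% with sgNT in equal-length lists. The chromosome 1 excess was uneven over peak strength, with each list divided into 4 equal parts by strength: from the weakest part to the strongest, chromosome 1 held 16.3, 8.37, 7.06 and 8.47% of the peaks with sgB2 and 8.21, 6.67, 6.51 and 6.21% with sgNT. Gains on chromosome 1 with sgB2, including Fmn2 and Rgs13, therefore sit on a shift of the whole chromosome. On X all 14 bins had a lower mean share with sgB2, but in only 6 of 14 did every sgB2 library lie below every sgNT library.

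**Figure D4:**
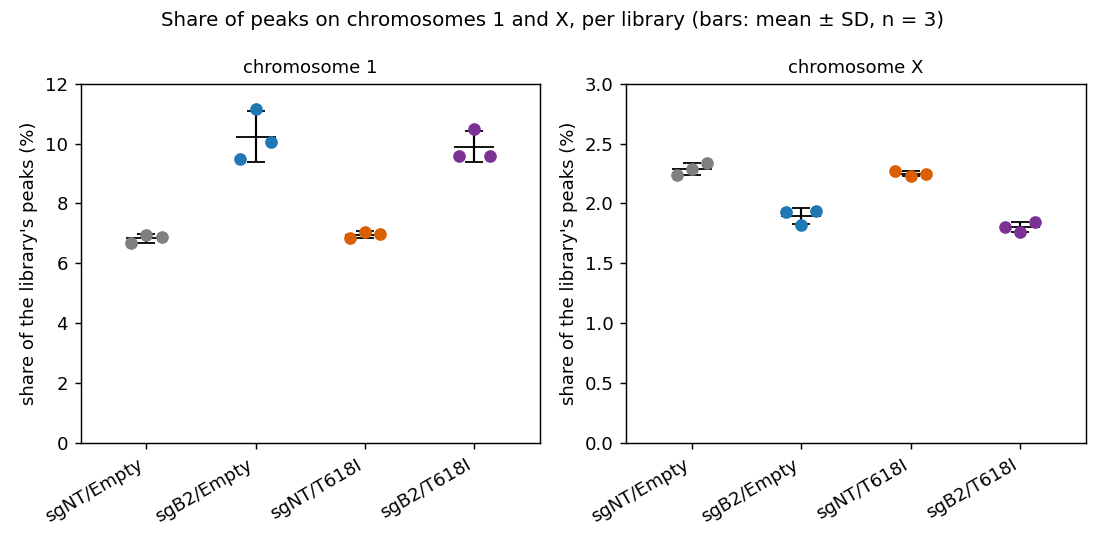
Share of each library's peaks on chromosome 1 (left) and X (right), in percent, by group. Points are libraries and bars the mean ± SD (n = 3); on chromosome 1 the 6 sgB2 libraries lie between 9.48 and 11.2% and the 6 sgNT libraries between 6.67 and 7.05%.

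Few members of the fixed lists moved with the Asxl1 guide. Mature neutrophil genes had none of 20 past the test and none adjusted over the list alone (median -0.03, camera adjusted p = 0.344). In the secondary and tertiary granule list none of 20 passed the test, 1 fell adjusted over the list alone and the median was -0.16 (camera adjusted p = 0.00917; adjusted p = 0.333 with an estimated correlation). In that list S100a9 had -0.31 ± 0.08 (limma adjusted p = 0.0606) and Ngp, a neutrophil granule protein gene, -0.32 ± 0.14 (adjusted p = 0.253). In the stem and progenitor list Bcl11a fell (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.332), with Gata2 at 0.38 ± 0.11 (adjusted p = 0.0816) and Myb at -0.43 ± 0.13 (adjusted p = 0.0995). Single members fell in the macrophage list (Mpeg1, -0.38 ± 0.09) and the JAK-STAT list (the cyclin gene Ccnd2, -0.71 ± 0.16), with the same counts adjusted over each list alone. Camera gave adjusted p = 0.143 and 0.338 for these lists. Single members rose in the primary granule list (Ms4a3, 0.53 ± 0.13), the mast cell list (its neighbour Ms4a2, the same window) and the erythroid list (the transcription factor Gata1 on X, 0.45 ± 0.11), with the same counts adjusted over each list alone and camera adjusted p = 0.244, 0.444 and 0.372. Ms4a3 and Ms4a2 had the opposite sign with stricter peaks and in equal-length lists, and Ms4a3 also in a 10 kb window. The primary granule list as a whole had a median of -0.12, and it passed downward with a 10 kb window (adjusted p = 0.00238; adjusted p = 0.0429 with an estimated correlation) and with stricter peaks (adjusted p = 0.0358; adjusted p = 0.129 with an estimated correlation). No member of the lymphoid, myeloid transcription factor, Polycomb and ASXL-BAP1, interferon, inflammatory or housekeeping lists passed (1 lymphoid and 1 interferon gene fell adjusted over the list alone). For these camera gave adjusted p = 0.496, 0.626, 0.563, 0.266, 0.702 and 0.496.

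With the empty vector (3 sgB2/Empty against 3 sgNT/Empty libraries), sgB2 raised coverage around 35 genes (28 loci) and lowered it around 19 (17 loci). Fam155a rose from no coverage to 1.48 ± 0.18 kb (SD, n = 3; log2 change 1.98 ± 0.20, limma adjusted p = 0.000341). Gains followed at Fmn2 (1.93 ± 0.30), the neighbours B3gat1 and Glb1l2 (1.9 ± 0.32) and Nfatc2, a calcium-responsive transcription factor (1.79 ± 0.23). Amotl2 fell from 2.08 ± 0.66 to 0.14 ± 0.23 kb (-2.05 ± 0.29). Losses followed at Bcl11a (-1.62 ± 0.21), BC107364 (-1.50 ± 0.28), Scml4, a Polycomb-related gene (-1.46 ± 0.28) and Calml3 (-1.40 ± 0.26). Bcl11a is a member of the stem and progenitor list, and no list passed camera with the chosen settings (smallest adjusted p = 0.439). With a 10 kb window secondary and tertiary granule genes fell as a list (adjusted p = 9.8e-05; adjusted p = 0.019 with an estimated correlation). The count of 54 genes became 24 without chromosomes 1 and X, 15 without sgNT/Empty replicate 2, and 1 without scaling, while leaving out sgNT/Empty replicate 1 gave 130.

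With T618I present (3 sgB2/T618I against 3 sgNT/T618I libraries), sgB2 raised coverage around 25 genes (21 loci) and lowered it around 30 (25 loci). Akap6 rose from 0.28 ± 0.04 to 2.94 ± 0.59 kb (SD, n = 3; log2 change 2.14 ± 0.30, limma adjusted p = 0.00438). It was followed by Gask1b (1.67 ± 0.28), Dst (1.57 ± 0.24) and Sh3bp4 (1.51 ± 0.22) on chromosome 1, and Mras (1.49 ± 0.23). Pls3 (-2.19 ± 0.39), Spp1 (-1.96 ± 0.22), Amot (-1.70 ± 0.17), Gm5294 (-1.64 ± 0.33) and Etv1, an ETS transcription factor (-1.53 ± 0.20), fell. So did Bcl11a (-1.36 ± 0.21) and Mpeg1, a pore-forming protein gene of macrophages (-0.62 ± 0.13, adjusted p = 0.0488). No mature neutrophil gene passed, with or without adjustment over the list alone (median -0.08, camera adjusted p = 0.194). For secondary and tertiary granule genes the median was -0.16 with none past the test and 1 that fell adjusted over the list alone (camera adjusted p = 0.00334; adjusted p = 0.183 with an estimated correlation). For primary granule genes the median was -0.17 with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.0559). This list passed, downward, in 9 of 21 alternatives, but with an estimated correlation only for a 10 kb window (adjusted p = 1.7e-06; adjusted p = 0.0139 with an estimated correlation). The call of the secondary and tertiary granule list was lost without sgB2/T618I replicate 3 (adjusted p = 0.323). The count of 55 genes became 23 without chromosomes 1 and X, 9 without sgNT/T618I replicate 1 and 216 in equal-length lists. Without scaling 1 gene rose and 4 fell. These are counts, and do not say how many of the 55 genes were called again.

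By region, sgB2 gained 260 and lost 349 regions with the empty vector, and gained 326 and lost 684 with T618I. The 2 backgrounds shared 28 gains, where 2.28 would be shared if the lists were independent, and 67 losses, where 6.43 would be. Both expectations again count regions that could not be gained or lost, and are too low. In equal-length lists the balance turned, with 46 shared gains and 31 shared losses. The strongest shared gain lay within 1 kb of an end of Pcbp3, an RNA-binding protein gene (chromosome 10, 76961713 to 76962271, mm10), and others lay inside Arhgef12 (chromosome 9, 43096387 to 43096765) and 47040 bp from the lipoprotein lipase gene Lpl (chromosome 8, 68953972 to 68954302). Shared losses lay inside Ppp1r9a (chromosome 6, 4973034 to 4973668), within 1 kb of an end of Tbc1d8b (X, 139684633 to 139685823) and of Rpgr (X, 10216260 to 10217012), and within 1 kb of an end of the imprinting regulator gene Zfp57 (chromosome 17, 37009421 to 37009934). With the empty vector a region 4091 bp from Ngp (chromosome 9, 110415176 to 110415717) was lost, and with T618I regions 25155 bp from the chemokine receptor gene Ccr1 (chromosome 9, 123936684 to 123936971) and inside Nrp2 (chromosome 1, 62760103 to 62760440). Chromosome 1 held 42.9% of the shared gains and X 14.9% of the shared losses, against 8.69% and 2.08% of all regions. The exact stratified test, with the same limit, passed 0 of 37113 regions. At an unadjusted p under 0.05, 109 were found more often and 246 less often with sgB2. Of the testable regions 5% is 1174, or 899 among those found in at least 3 libraries, which again gives no chance level. In equal-length lists the counts with the empty vector were 391 gained and 273 lost and with T618I 377 and 388, and without sgNT/Empty replicate 1 the losses with the empty vector rose to 2108.

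Cells with both mutations were compared with the control (3 sgB2/T618I against 3 sgNT/Empty libraries). Coverage rose around 329 genes (204 loci) and fell around 244 (166 loci). F2rl2 (2.45 ± 0.24, limma adjusted p = 0.000105), Akap6 (2.22 ± 0.30), Fam155a (2.21 ± 0.20), the carbonic anhydrase-related gene Car8 (2.09 ± 0.21) and Nfatc2 (1.91 ± 0.23) rose most. Col4a6, a basement membrane collagen gene on X (-1.99 ± 0.39), Spp1 (-1.94 ± 0.22), Ttr (-1.93 ± 0.28), Calml3 (-1.88 ± 0.26) and Amot (-1.81 ± 0.17) fell most. Of the mature neutrophil list 5 rose, among them Retnlg (1.01 ± 0.23) and Il1r2 (0.97 ± 0.20). In it 7 rose adjusted over the list alone (median 0.23, camera adjusted p = 1.3e-06; adjusted p = 0.0452 with an estimated correlation). In the secondary and tertiary granule list 4 rose, including S100a9 (0.73 ± 0.12) and Cd177 (0.84 ± 0.22), with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.286 with an estimated correlation). Primary granule genes had 3 that fell, Mpo (-0.66 ± 0.13), Prtn3 (-0.56 ± 0.12) and Elane (-0.54 ± 0.13; camera adjusted p = 0.0494; adjusted p = 0.128 with an estimated correlation). The lymphoid list, where Ebf1 and Vpreb1 fell, also had camera adjusted p = 0.0494, with adjusted p = 0.128 with an estimated correlation. In the inflammatory list Il6 rose (1.56 ± 0.20; camera adjusted p = 0.00517; adjusted p = 0.0452 with an estimated correlation). That call was lost with a 10 kb window (adjusted p = 0.104), stricter peaks (adjusted p = 0.052) and equal-length lists (adjusted p = 0.113). The calls of the primary granule and the secondary and tertiary granule lists were lost in 14 and 17 of 21 alternatives. By region 1084 were gained and 522 lost, including a gain inside the calcium channel subunit gene Cacng8 (chromosome 7, 3411166 to 3411749) and a loss 22382 bp from Kmt2e (chromosome 5, 23410115 to 23410654). The count of 573 genes became 210 with a 10 kb window and 243 without sgB2/T618I replicate 1. Without chromosomes 1 and X 191 genes rose and 199 fell, without scaling 18 rose and 6 fell, and without sgNT/Empty replicate 1 1126 regions were gained and 2040 lost.

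Last, the interaction asked whether the Asxl1 guide changed the response to T618I (all 12 libraries). By limma 1 of 15286 genes passed, Amot (chromosome X, 145446424 to 145505966), where the call was lost in 14 of 22 alternatives. It had 1.27 ± 0.30, 1.31 ± 0.16 and 1.12 ± 0.08 kb in sgNT/Empty, sgB2/Empty and sgNT/T618I and no coverage in the 3 sgB2/T618I libraries (log2 interaction -1.74 ± 0.24, adjusted p = 0.0198). Of all genes 751 genes had an unadjusted p under 0.05. Cd177 (-1.20 ± 0.31), Retnlg (-1.09 ± 0.32) and Ebf1 (-1.04 ± 0.26), named for their T618I changes, had smaller changes or larger losses with sgB2 that did not pass (adjusted p = 0.685, 0.777 and 0.666). No list passed camera with the chosen settings: mature neutrophil genes had a median of -0.05 (adjusted p = 0.787), secondary and tertiary granule genes -0.01 (adjusted p = 0.787) and primary granule genes -0.13 (adjusted p = 0.715). Primary granule genes passed with a 10 kb window (down, adjusted p = 0.000243; adjusted p = 0.0486 with an estimated correlation), and secondary and tertiary granule genes with stricter peaks (down, adjusted p = 0.0147; adjusted p = 0.246 with an estimated correlation). A difference between the backgrounds in these genes is therefore left open. An interaction that does not pass does not show that T618I acted alike in both backgrounds.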

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

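The rule for a value that differs between groups and the count of peaks outside the standard chromosomes were set before the result was seen, while most tests of explanations were chosen only after it was seen. Amot had a log2 interaction of -1.74, the only gene past the interaction test, and lies on the X chromosome, which held a smaller share of peaks in all sgB2 libraries. Its call was lost in 14 of 22 alternatives. Other splits of the 12 libraries gave up to 78 genes against the 1 observed, and 11 of 100 splits, the real one included, gave as many. A single call like this was therefore not rare among splits, which also mix libraries of different groups.

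In sgB2/Empty replicates 2 and 3, 0.735% and 0.656% of the peaks (187 and 171) lay on contigs outside the standard chromosomes, above the sgNT/Empty maximum of 0.645%. These peaks were not used. No library was tested for being an outlier within its group of 3. sgNT/Empty replicate 1 had the shortest list (18484 peaks), and leaving it out moved 4 of the 7 region counts more than leaving out any other library.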

How the results depend on the processing

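Most alternatives were fixed before the data were examined; the tests without chromosomes 1 and X, those of the chromosome shares and those with 1 list member per locus were chosen only after the result was seen. Of the list results 1025 stayed the same, 75 became weaker, 31 stronger and 1 reversed. Gene counts stayed in 111 cases and moved in 78, and region counts stayed in 95 and moved in 29. These cases compare counts only, and a count that stayed can hold other genes. Without scaling the T618I effect had 853 genes, of which 544 were among the 992 called in the chosen setting. Of the named gene results 3106 stayed, 613 became weaker, 6 stronger and 11 reversed. The 28 chromosome share results stayed by their exact p before adjustment. With stricter peaks neither chromosome 1 nor X passed after adjustment with sgB2 (exact test, adjusted p = 0.0667 and 0.075). Of the similarity results 54 stayed and 6 became stronger. The library tests of 3 against 3 could not pass in any setting, and the per-region factor tests only if very many regions reached the smallest p (3712 in the chosen setting), so their lack of calls is no evidence of stability. Although no library measure passed in any alternative (smallest adjusted p 0.16), 18 of 32 differences changed sign in some alternative. Motif content was not run for lack of a genome.

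Regions. Asking only for at least 2 more libraries of one group gave 5810 regions for T618I in sgNT cells, 4401 for sgB2 in Empty cells, 5174 for sgB2 in T618I cells, 6142 for T618I in sgB2 cells and 6662 for both mutations. Keeping only peaks with −log10 q of at least 4 gave 326 for sgB2 in Empty cells, 924 for T618I in sgB2 cells, 985 for both mutations and 49 for the sgB2 effect. Asking for peaks over 50% of a region gave 62 for the sgB2 effect. Leaving out 1 library loosens the criterion by construction. It gave 1408 to 2508 for T618I in sgNT cells, 609 to 2391 for sgB2 in Empty cells, 1606 to 3166 for both mutations and 102 to 181 for the sgB2 effect, highest without sgNT/Empty replicate 1. It gave 1010 to 2165 for sgB2 in T618I cells, highest without sgB2/T618I replicate 2, and 1540 to 2703 for T618I in sgB2 cells, highest without sgB2/T618I replicate 3.

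Genes by scaling. Without scaling 59 genes were called for T618I in sgNT cells, 36 for T618I in sgB2 cells, 24 for both mutations, 22 for the sgB2 effect, 1 for sgB2 in Empty cells and 5 for sgB2 in T618I cells. Quantile normalization gave 371 for T618I in sgB2 cells and 0 for the interaction. With the log2 number of peaks as covariate the T618I effect had 642. In equal-length lists T618I in sgNT cells had 510, sgB2 in T618I cells 216 and the interaction 4; the T618I effect had 686 up and 546 down, T618I in sgNT cells 318 up and 192 down, and T618I in sgB2 cells 198 up and 157 down.

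Genes by window, filter and fit. With a 10 kb window the counts were 56 for T618I in sgNT cells, 21 for sgB2 in Empty cells, 26 for sgB2 in T618I cells, 102 for T618I in sgB2 cells, 210 for both mutations, 372 for the T618I effect and 122 for the sgB2 effect. With strict peaks they were 12 for sgB2 in Empty cells, 338 for both mutations, 122 for the sgB2 effect and 9 for the interaction. A pseudocount of 100 bp gave 32 for sgB2 in Empty cells and 2 for the interaction, and 2000 bp gave 0 for the interaction. Fitting only the 6 libraries of a comparison gave 361 for both mutations, 24 for sgB2 in Empty cells and 115 for sgB2 in T618I cells. Without chromosomes 1 and X 191 were called for the sgB2 effect, 24 for sgB2 in Empty cells, 23 for sgB2 in T618I cells and 0 for the interaction.

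Genes by library left out. The counts ran from 63 (without sgNT/T618I replicate 2) to 270 for T618I in sgNT cells, from 15 (sgNT/Empty replicate 2) to 130 (sgNT/Empty replicate 1) for sgB2 in Empty cells, and from 9 (sgNT/T618I replicate 1) to 108 for sgB2 in T618I cells. They ran from 92 (sgB2/Empty replicate 1) to 382 for T618I in sgB2 cells and from 243 (sgB2/T618I replicate 1) to 643 for both mutations. The T618I effect ran from 587 to 1118 and the sgB2 effect from 221 to 585, both lowest without sgNT/T618I replicate 1, and the interaction from 0 to 3.

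Named genes. Of the T618I effect, Gp9 changed to 0.12, Eed to -0.0583 and Snrpd3 to -0.15 with a 10 kb window, and Gp9 to 0.0353 with strict peaks. Csf3r in sgB2 cells changed to -0.13 with a 10 kb window and -0.0135 in equal-length lists. Of the sgB2 effect, Ms4a3 changed to -0.0910 with a 10 kb window, and Ms4a2 and Ms4a3 to -0.13 with strict peaks and -0.15 in equal-length lists.

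Similarity. The sgB2 difference was 0.0351 in equal-length lists (exact p = 0.02) and 0.0155 to 0.0446 with 1 library left out, where 5 of 12 fits passed.

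Gene lists with T618I (camera adjusted p). Primary granule genes had 0.0344 with a 10 kb window, 0.0203 with strict peaks and 0.0103 in equal-length lists, where the main value did not pass; with an estimated correlation these were 0.131, 0.0819 and 0.0882. Secondary and tertiary granule genes had 0.138 with strict peaks, and with both mutations 0.632 in the opposite direction. JAK-STAT targets had 0.138 with strict peaks, 0.0642 in equal-length lists and 0.00759 to 0.164 with 1 library left out. Interferon genes had 0.788 with strict peaks, 0.0737 without scaling, 0.917 in equal-length lists, 0.122 with the covariate, 0.0533 without chromosomes 1 and X and 0.0199 to 0.0997 with 1 library left out. Lymphoid genes had 0.401 with strict peaks, 0.151 with a 10 kb window, 0.441 in equal-length lists, 0.0512 with the covariate, 0.0527 without chromosomes 1 and X and 0.0248 to 0.234 with 1 library left out. Developmental Polycomb targets had 0.00443 without scaling, and 0.545 with an estimated correlation.

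Gene lists with sgB2 (camera adjusted p). The secondary and tertiary granule list had 0.0752 without scaling and 0.00343 to 0.2001 with 1 library left out. With strict peaks mast cell genes had 0.00686, mature neutrophil genes 0.0418, macrophage genes 0.0180 and primary granule genes 0.0358. With an estimated correlation all 4 were lost (0.104, 0.278, 0.104 and 0.129). With a 10 kb window lymphoid genes had 0.0272, macrophage genes 0.00346 and primary granule genes 0.00238. With an estimated correlation the first was lost (0.0907) and the others kept (both 0.0429).

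Gene lists in single comparisons (camera adjusted p). For sgB2 in T618I cells primary granule genes passed downward without scaling (0.0309), with quantile normalization (0.0304), the covariate (0.0183), a 10 kb window (1.7e-06), strict peaks (0.0244) and in 4 fits with 1 library left out (0.0158 to 0.0486). With an estimated correlation only the 10 kb window kept the call (0.0139; the others 0.0784 to 0.959). With strict peaks mature neutrophil genes passed there too (0.0244), but not with an estimated correlation (0.222). For T618I in sgB2 cells primary granule genes passed downward with quantile normalization (0.0319), the covariate (0.0271), a 10 kb window (0.000494), strict peaks (0.0122), equal-length lists (0.0088) and without sgB2/Empty replicate 1 (0.0363). Again only the 10 kb window kept the call with an estimated correlation (0.0285; the others 0.0636 to 0.207). For T618I in sgNT cells they passed downward in equal-length lists (0.0469), but not with an estimated correlation (0.172).

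Pairing. Replicate numbers gave no clear sign of pairs, but pairing was not excluded. Residual correlations of the same number in different groups ran from -0.158 to 0.216, and 4 of 18 were over 0.1. Their median was 0.00859, against -0.0161 for different numbers. Of 12 libraries, 6 matched best with their own number. A replicate block gave 255 genes for T618I in sgNT cells, 51 for sgB2 in Empty cells, 56 for sgB2 in T618I cells, 247 for T618I in sgB2 cells, 610 for both mutations, 1036 for the T618I effect, 457 for the sgB2 effect and 1 for the interaction. It left region counts unchanged by construction, and for library measures gave a smallest adjusted p of 0.375.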

Other observations

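The tests for extra copies of chromosome 1 and fewer copies of X were written before their results were seen, and all other tests of explanations here were chosen only after the pattern was seen.

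The larger share of chromosome 1 peaks in sgB2 libraries was not explained by list length, because the ratio was still 1.24 in equal-length lists, nor by a limited set of loci, because all 20 bins were higher. Extra copies of chromosome 1 in the sgB2 cells could explain it: of 875 chromosome 1 regions found in all 12 libraries 89.6% ranked higher in sgB2 libraries, against 41.2 to 50% on the other autosomes. A chromosome-wide opening without a change in copies, or a drift of the sgB2 cells unrelated to Asxl1, might do the same and cannot be told apart without a karyotype or reads outside peaks. The excess was largest among the weakest peaks of a list, which the copy test did not address. For X, 49.7% of 290 shared regions ranked higher, so the regions found in all 12 libraries gave no sign of fewer copies of X. From the weakest part of a list to the strongest, X held 1.285, 2.167, 2.482 and 1.462% of the peaks with sgB2. With sgNT it held 2.301, 2.766, 2.511 and 1.502%. The smaller share thus lay mainly among the weaker peaks, which the copy test did not address for X either. Whether fewer copies of X explain it was therefore left open.

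The rise of mature neutrophil genes with T618I was not due to list length (median 0.47 in equal-length lists). Nor was it due to neighbouring members that share peaks (camera adjusted p = 0.00505 with 1 member per locus and an estimated correlation). The macrophage and primary granule lists did not share the rise (the higher of their medians was 0.0065). They do not stand for all myeloid genes, so a rise around myeloid genes in general was tested only for these lists. Together with the fall around Mpo and Prtn3, the rise of mature neutrophil genes may reflect a larger fraction of maturing cells at 48 h, or a change within cells of the same stage. Peak lists of a mixed population cannot separate these, and single-cell data or sorted stages could.

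The surplus of regions gained over lost with T618I was smaller in equal-length lists. There 61.8% of the regions of the T618I effect were gains, against 88.8% in the deposited lists and 85.8% with stricter peaks. The value of 61.8% lies between those expected from a length artefact and from a real surplus, so the test could not tell. Equal-length lists also drop weaker peaks, so they do not isolate list length. Deeper libraries or read counts in common regions might settle it.

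The libraries were also regrouped, to see how many calls other splits of the same libraries give. Other splits mix libraries of both groups, so a real difference enters their spread and can lower their counts. The counts are therefore no measure of the spread alone. For genes, the highest other split had 0 against the real 228 for T618I in sgNT cells, 35 against 54 for sgB2 in Empty cells, 0 against 55 for sgB2 in T618I cells, 2 against 245 for T618I in sgB2 cells and 1 against 573 for both mutations. In these the real split was 1 of 10, too few to reach a share under 0.05. For the T618I effect it was 19 against 992 and for the sgB2 effect 3 against 432, the real split being 1 of 100 in each.

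For regions, the highest other split had 455 against 1408 for T618I in sgNT cells, 575 against 1010 for sgB2 in T618I cells, 469 against 1540 for T618I in sgB2 cells and 1023 against 1606 for both mutations, each 1 of 10. For sgB2 in Empty cells another split gave 967 against 609, and 2 of 10 were as large, whereas in equal-length lists the real split had 664 against 320 and was 1 of 10. Whether the spread between libraries alone could give the region changes of sgB2 in Empty cells was therefore left open. For the T618I effect it was 17 against 286 and for the sgB2 effect 16 against 95, each 1 of 100.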
